A study of Mus musculus with 5 samples.

How the data were processed

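ATRX ChIP-seq peak lists of 4 mouse neuron libraries were analysed: mCherry at DIV14 (the control), TBC1D3 at DIV14, MICAL1-M1 at DIV14 and mCherry at DIV7. An input DNA sample of the series had no peak list and was not analysed here. Per the labels' protocols, chromatin was prepared with an enzymatic kit, immunoprecipitated with an ATRX antibody, sequenced from both ends on an Illumina HiSeq, and input DNA served as the background. Per the submitters' processing notes, Bowtie 1.3.0, SAMtools 1.9, MACS 1.4.2 and ChIPseeker 1.26.2 were used; their roles, settings and the genome build are not given in the sources used here. MACS 1.4.2 does not write the narrowPeak layout with q-values that the lists have, so which caller made them is uncertain. The meaning of fold, p and q was taken from that layout and from the fit of p to a Poisson tail. Each list belongs to 1 library, so peaks were not called on pooled samples.

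The deposited lists have 10 columns without a header and follow the narrowPeak layout. The authors' score per peak equals 10 times the -log10 p cut to a whole number in every row. The deposited fold per peak is a ratio of the ChIP pileup to the caller's local background. The deposited -log10 values per peak are those of an uncorrected p-value and of a q-value corrected over the genome. The largest p in each list was just under 0.05, so the lists were made without a correction for multiple testing, and 57.0% of the control's peaks, 98.1% of those of TBC1D3, 94.4% of those of MICAL1-M1 and 97.6% of those of mCherry at DIV7 have a q of 1. The remaining deposited column, the summit offset in bp, gave the summit position. Folds are the authors' own and were used within a list to rank and describe peaks; the medians given for hotspot regions stand for each list on its own and show no change between lists.

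Read totals were not analysed here. The depth was read from the peaks: fold and p of a peak fit a whole pileup and a Poisson background, within 0.001 in log10 p, for 99.97% to 99.99% of rows, which gives a genome background of 3.56 fragments in the control, 1.22 in TBC1D3, 2.61 in MICAL1-M1 and 1.28 in mCherry at DIV7. The shortest peak was 287 bp in the control, 227 bp in TBC1D3, 282 bp in MICAL1-M1 and 230 bp in mCherry at DIV7. Exact binomial intervals at 95% cover counting error only and say nothing of the spread between cultures, which 1 library per group cannot show. No p-value was computed between conditions.

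Gene positions came from the RefSeq table of GRCm38.p6. The build was settled from the data: scaffold names are those of GRCm38, and summits were more frequent at gene ends than 20 kb away on 20 or 21 of 21 chromosomes in each library. The table gives the start and end of each gene without strand, exons or sequence. The promoter planned before the data were examined was therefore replaced by a window of 1 kb on each side of both gene ends, 1 of which is the start of transcription; exon classes, matching on promoter GC content and sequence at summits were not run. Gene bodies run from gene start to gene end.

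Peaks on chromosomes 1 to 19, X and Y were compared by overlap of at least 1 bp and set beside 100 shuffles within chromosomes (bedtools 2.31.1), over the range that the peaks cover. The share of summits at gene ends was set beside the first 20 of these shuffles. Genes with a summit in a gene-end window were counted among 21887 protein-coding genes. The share of each of 23 gene lists, and its difference from the control, was placed among 10000 random gene lists of the same size matched on gene length in 10 bins; 1000 random lists were drawn under most of the alternative settings. A difference from the control also depends on the control's share, since a list with few occupied genes there has little to lose and a list with many has much. Differences were therefore also set beside random lists matched on gene length and on whether the control's list occupies the gene (control-matched lists), as an alternative added after the data were seen. Genes that are often occupied in every library tend to lie low in the first comparison and high in the second. A percentile describes these libraries and is no p-value, since genes are not replicates. The lists were fixed before the data were examined and cover glutamate synapses, presynaptic release, inhibitory synapses, voltage-gated channels, immature neurons and axon guidance, neuronal adhesion, immediate early genes, chromatin and ATRX partners, imprinted genes, Zfp zinc finger genes, clustered protocadherins, olfactory and vomeronasal receptors, ribosomal proteins, oxidative phosphorylation, clustered histones, developmental transcription factors and Wnt genes, MICAL, RAB and actin regulators, and markers of astrocytes, oligodendrocytes, microglia, fibroblasts with endothelium, and progenitors. Of the 49 symbols of the imprinted list 48 were found in the table and 41 were protein-coding genes there, and of the 38 symbols of the immediate early list 37 were found.

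Genes gained in common by comparisons that share the control were set beside the product of the list sizes over the number of genes and beside 100 simulations that redistributed each gene's detections among the 3 libraries while keeping their expected totals. The text names, per comparison and direction, the 10 genes with the highest fold at a gene end, up to 4 gained and 4 lost members of each list, and always Atrx, Daxx, Mical1, Dlg4, Syn1, Grin2a, Grin2b, Gria2, Camk2a, Dcx and Tubb3; predicted genes and genes sharing a peak with a named gene were left out, and some genes that this rule takes are not reported here.

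Alternatives fixed before the data were examined were a -log10 q of at least 5, equal list sizes, peaks merged within 100 bp, all sequences, an overlap of 50% of both peaks, summits within 100 bp, a 3 kb window, any base of a peak in the window, all annotated genes, no summit within 5 kb, the gene body and unmatched random lists. A q of at most 0.05, the 4000 strongest peaks per list, the removal of hotspots and control-matched lists were added after the data were seen. The steps were tested on simulated data: the pileup was recovered for 3000 of 3000 simulated peaks, and among 21887 genes a list of 60 genes with a planted fall of up to 25 percentage points lay at or below percentile 2.5 in 83 of 100 simulations. Without an effect, 9 of 100 such lists lay outside percentiles 2.5 to 97.5. Among control-matched lists, the numbers were 99 of 100 and 6 of 100. In these simulations occupancy depended on gene length alone and was drawn separately for each library. They lack the occupancy that real genes share between libraries, so these rates do not carry over to the real gene lists. Scripts used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.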

Results

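ATRX, a chromatin remodeller that works with the histone chaperone DAXX at heterochromatin and repeats, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in cultured mouse neurons. The neurons came from late C57BL6/J embryos and were given lentivirus on day 5 in vitro. There were 4 ChIP libraries, 1 per group, so no value below has a replicate error. The control carried mCherry, a fluorescent protein, and was taken at day 14 in vitro (DIV14). Of the other DIV14 libraries, 1 carried TBC1D3, a gene found in humans and other hominoids but not in mice, and 1 a construct labelled MICAL1-M1, MICAL1 being an enzyme that oxidises actin. The last library carried mCherry at day 7 (DIV7) and stands for young neurons in the series design. By its title the series asked how a hominoid-specific signalling axis sets the pace of synapse maturation. The peak lists hold 96670 peaks for the control, 199059 for TBC1D3, 141387 for MICAL1-M1 and 213982 for mCherry at DIV7. Every list reaches an uncorrected p of 0.05, and the share of peaks with a q of at most 0.05 was 4.19% in the control (95% exact binomial interval 4.06 to 4.32), 0.205% in TBC1D3 (0.186 to 0.226) and 0.236% in mCherry at DIV7 (0.216 to 0.258). In MICAL1-M1 it was 0.463%. The background pileup recovered from the peaks was 3.56 fragments in the control, 1.22 in TBC1D3, 2.61 in MICAL1-M1 and 1.28 in mCherry at DIV7, so the lists rest on different depths.

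**Figure D1:**
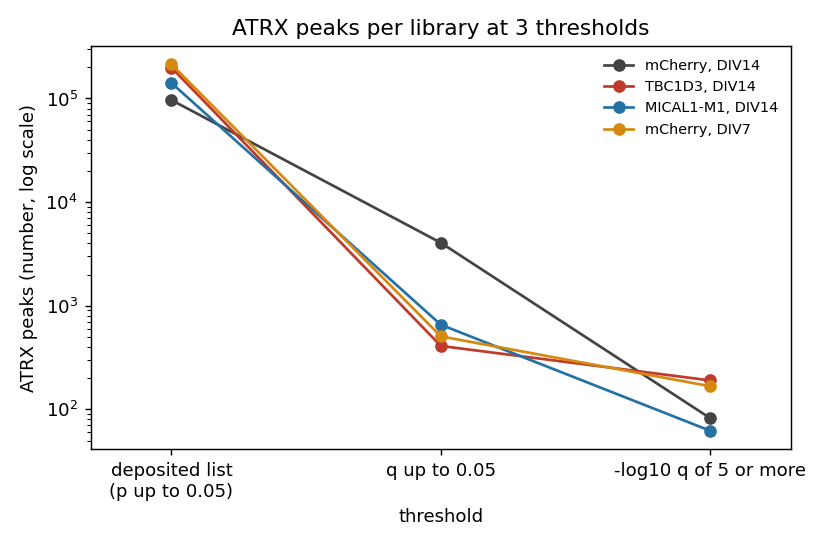
Number of ATRX peaks (log axis) in each of the 4 libraries at 3 thresholds; each point is 1 library. The control has the fewest peaks in the deposited lists, 96670, and the most at a q of at most 0.05, 4049.

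In control neurons, ATRX summits were more frequent at gene ends than shuffled peaks were, though most lay elsewhere. Of the control's summits, 47.5% lay in the rest of gene spans and 42.6% outside genes. Summits fell within 1 kb of an end of a protein-coding gene for 9.95% of the control's peaks (9.76 to 10.1), against 2.98% for peaks shuffled within chromosomes, and for 40.8% of its peaks with a q of at most 0.05. Clustered histone genes had a gene-end summit in 45 of 67 cases, immediate early genes in 29 of 37, ribosomal protein genes in 56 of 84 and subunits and assembly factors of oxidative phosphorylation in 64 of 96; each of these shares lay above all random gene lists matched on gene length (percentile 100). Postsynaptic glutamate genes were occupied in 44 of 60 cases (percentile 99.9) and presynaptic release genes in 40 of 57 (percentile 99.5). Genes of inhibitory synapses (22 of 38, percentile 79.8) and of chromatin and ATRX partners (38 of 64, percentile 87.8) lay less high. At a q of at most 0.05, a threshold chosen after the data were seen, 1853 genes were occupied in the control. Postsynaptic genes were then occupied in 9 of 60 cases (percentile 74.4) and no longer stood apart from random lists. Presynaptic genes were occupied in 11 of 57 cases (percentile 95.2), and oxidative phosphorylation genes lay just under them. Immediate early, clustered histone and ribosomal protein genes stayed higher (percentiles 99.995, 100 and 99.8). The strongest gene-end peak by fold enrichment lay at Egr1, an activity-induced transcription factor, on chromosome 18 from 34859058 to 34862628 (GRCm38 positions), with 8.61-fold enrichment over the caller's background; Egr1 was singled out after its values were seen. Olfactory receptor genes, which neurons of the brain mostly keep silent, were occupied in 10 of 1106 cases (percentile 0), and the list of Hox, Pax, Lhx, Gata, Wnt and related developmental genes in 35 of 160 (percentile 0).

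**Figure D2:**
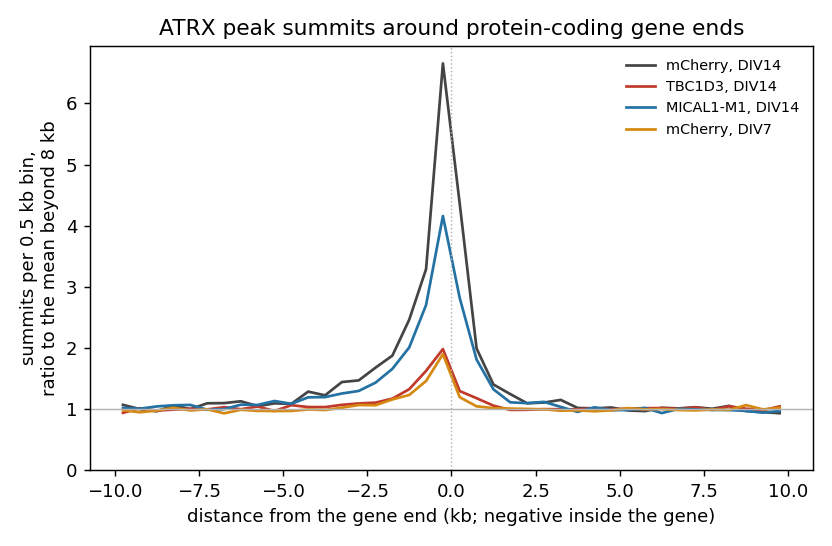
Summits per 0.5 kb bin around the ends of protein-coding genes, divided by the mean of bins beyond 8 kb; the x axis is the distance from the gene end in kb, negative inside the gene, and each line is 1 library. In the bin just inside the gene the ratio reached 6.66 in the control, 4.16 in MICAL1-M1 and 1.98 in TBC1D3, and mCherry at DIV7 lay just under TBC1D3.

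With TBC1D3, 33.4% of all protein-coding genes had an ATRX summit within 1 kb of their ends, against 42.3% in the mCherry control of the same age. The order turned in a 3 kb window (57.7% against 53.0%) and over all annotated genes (29.2% against 27.6%). Of the TBC1D3 summits 4.07% lay within 1 kb of a gene end, against 2.96% for shuffled peaks. Random placement thus gives most of this share, and a summit at a single gene of this list is weak evidence. Within 1 kb the developmental list rose from 35 to 80 of 160 occupied genes, with Gata4, Foxc2, Foxe3 and Hoxd11 among the 58 genes gained. Random lists matched on gene length and on occupancy in the control (control-matched lists, chosen after the data were seen) had 49.9 occupied genes with TBC1D3, and the developmental list lay at percentile 100 of these as of lists matched on length alone. Presynaptic release genes went from 40 of 57 in the control (70.2%, 56.6 to 81.6) to 24 (42.1%, 29.1 to 55.9), at percentile 3.65 of the differences of lists matched on length alone and 44.2 of control-matched lists. Clustered histone genes went from 45 to 30 of 67, ribosomal protein genes from 56 to 35 of 84, oxidative phosphorylation genes from 64 to 35 of 96 and zinc finger genes of the Zfp series from 229 to 127 of 394. On length alone these 4 differences lay at percentile 0, and among control-matched lists at percentiles 99.3, 87.1, 67.7 and 11.7. Against unmatched random lists they lay at percentiles 3.82, 0.78, 0.04 and 0. The occupied histone genes rested on 33 peaks in the control and on 20 with TBC1D3. At equal list size 10 histone genes were occupied (percentile 0 on length alone, 28.3 control-matched). Postsynaptic glutamate genes were occupied in 36 of 60 cases against 44 (percentile 48.2 on length alone, 99.2 control-matched).

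Here a gene counts as gained when a summit lies within 1 kb of either end in the named library and none does in the control, and as lost in the reverse case; neither word stands for a tested change. Over the 21887 protein-coding genes, 3405 were gained and 5338 lost with TBC1D3, and 3914 were occupied in both lists. A 3 kb window turned this order, with 4774 gained and 3760 lost. Among lost synaptic genes were Snap25 and Syt1 of the vesicle fusion machinery (3.51-fold and 3.51-fold), the active zone gene Rims3 (3.51-fold) and the glutamate receptor gene Gria2. The sodium channel gene Scn2a was lost as well (4.60-fold in the control). Of the genes occupied in the control, 17 of 40 presynaptic and 29 of 44 postsynaptic ones stayed occupied, against 3914 of 9252 over all genes. In each of these lists 7 genes were gained. The named losses are therefore no sign of a loss particular to synaptic genes. Immediate early genes went from 29 to 20 of 37 (percentile 3.14 on length alone, 97.8 control-matched) and to 10 with lists of equal size (percentiles 0 and 74.95); Jun (control peak on chromosome 4 from 95052516 to 95054109, 5.04-fold), Klf4 and Klf10 were lost, and Egr1 was occupied in both. Among the highest control folds of lost genes were those of Cyp20a1, Rab40b and Zfp869 (5.26-fold each), followed by the activin receptor gene Acvr1 (5.25-fold) and by Ints14, Jun, Nr1d2, Urgcp and Zfp433 (5.04-fold each). The highest TBC1D3 folds among gained genes were those of Lars2, a mitochondrial leucyl-tRNA synthetase (5.93-fold, chromosome 9 from 123461803 to 123462238), and of Sfi1 (5.74-fold). Atl2, Spry2 and Vgll3 (4.51-fold each), Dner, a neuronal Notch ligand (4.50-fold), and Lrp1b (4.48-fold) followed with a q of at most 0.05. Aldh1b1, Art1 and Art3 (4.06-fold each) came next with a larger q. Whether the peaks at these gained genes, Lars2 and Sfi1 included, lie in repeated sequence was not tested. Markers of microglia were occupied in 6 of 20 cases against 1 (percentile 98.9 on length alone, 53.8 control-matched) and those of fibroblasts and endothelium in 10 of 20 against 6 (percentiles 98.7 and 93.4), the latter 3 against 6 with lists of equal size (percentiles 79.8 and 30.9).

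Of the control's peaks, 12.7% (12.5 to 12.9) were overlapped by a TBC1D3 peak, against 6.62% for shuffled peaks. At a q of at most 0.05 the order of peak numbers turned, with 329 TBC1D3 peaks on the assembled chromosomes for 4041 in the control, and 32 genes were occupied against 1853, too few to compare gene lists. With lists of equal size the developmental list had 46 occupied genes, against 35 in the control and 28.3 in control-matched lists (percentile 99.8), with the 4000 strongest peaks of each list it had 4 against 4, and over gene bodies the presynaptic list lay 7.02 percentage points above the control.

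**Figure D3:**
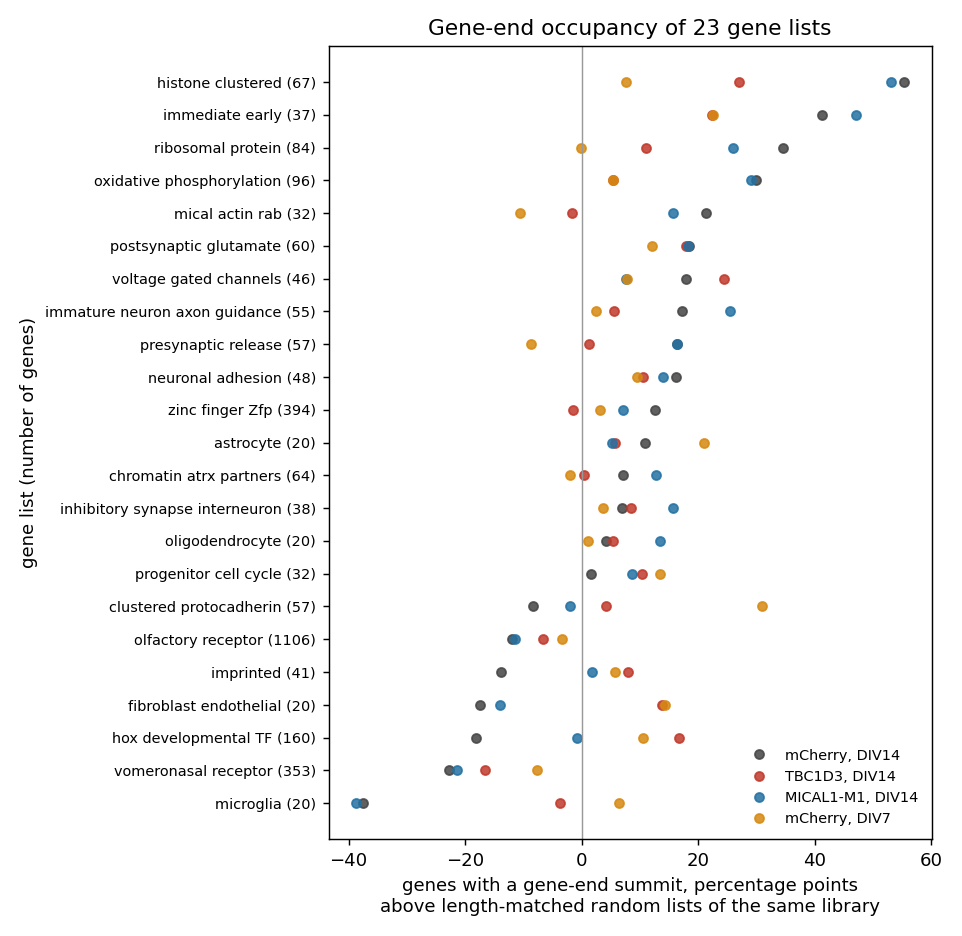
Share of each of 23 gene lists with a gene-end summit, in percentage points above the mean of random lists matched on gene length in the same library (x axis); each point is 1 library and the number of genes stands after the name. Clustered histone genes lie farthest to the right in the control, where 45 of 67 were occupied, and microglia markers farthest to the left, where 1 of 20 was.

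With MICAL1-M1, synaptic and immediate early genes in the full lists differed from the control no more than random lists matched on length did, and developmental genes lay above it. Presynaptic release genes were occupied in 38 of 57 cases against 40 (percentile 50.5 for the difference), postsynaptic glutamate genes in 42 of 60 against 44 (percentile 49.0), immediate early genes in 30 of 37 against 29, clustered histone genes in 44 of 67 against 45 and oxidative phosphorylation genes in 60 of 96 against 64. Among control-matched lists the presynaptic genes lay at percentile 95.6, postsynaptic genes at 97.4, immediate early genes at 99.99, and histone and oxidative phosphorylation genes at 100. Ribosomal protein genes were occupied in 47 of 84 cases against 56 (percentile 4.46 on length alone, 97.7 control-matched) and Zfp genes in 189 of 394 against 229 (percentiles 1.92 and 83.7). At equal list size 41 ribosomal protein genes were occupied (percentiles 1.45 and 94.6). The developmental list was occupied in 57 of 160 cases against 35, with Dlx5, Hoxa7, Wnt11 and Sox2 among the 36 gained; control-matched lists had 46.4 (percentile 100 on length alone, 97.7 control-matched). Microglia markers were occupied in 0 of 20 cases against 1 (percentiles 45.7 and 0.15) and fibroblast and endothelial markers in 6 of 20 against 6 (61.6 and 23.7).

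Over the 21887 genes, 2542 were gained and 3326 lost with MICAL1-M1, and 5926 were occupied in both lists. The highest MICAL1-M1 folds among gained genes were those of Dner (4.82-fold, chromosome 1 from 84694715 to 84696141), Ptma (4.68-fold), Api5 (4.46-fold), Golph3 (4.43-fold) and Socs4 (4.41-fold), then Adora1, an adenosine receptor (4.29-fold), and Bcor, Elmod3, Fgfr2 and Mrpl33 (4.15-fold each). Dner was also gained with TBC1D3. Of the list of axon guidance and immature neuron genes, occupied in 42 of 55 cases against 39 (percentile 86.1 on length alone, 99.8 control-matched), the guidance receptor gene Plxna2 (3.95-fold) and the growth cone gene Gap43 (3.88-fold) were gained at a q of at most 0.05, and Ncam1 and Cntn2 were lost. The highest control folds among lost genes were those of the remodeller gene Ino80 (5.58-fold), of Zfp869 (5.26-fold), Ints14 (5.04-fold) and the adenylate cyclase gene Adcy8 (5.02-fold). Mpzl1, Ufl1, Wdr36, Yif1b and Zkscan16 followed (4.82-fold each), then Trim28 (4.77-fold), which encodes a corepressor recruited by zinc finger proteins. Mical1 itself had a gene-end summit in the control (1.87-fold) and in none of the other lists. Atrx had one in MICAL1-M1 alone of the 4 lists (2.77-fold), and Daxx had one in MICAL1-M1 and in mCherry at DIV7. Atrx lies on chromosome X, where peaks were few in every list. None of these peaks at Mical1, Atrx and Daxx reached a q of at most 0.05.

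Of the control's peaks, 22.5% (22.3 to 22.8) were overlapped by a MICAL1-M1 peak, against 5.35% for shuffled peaks. At a q of at most 0.05 there were 625 MICAL1-M1 peaks on the assembled chromosomes, of which 29.1% (25.6 to 32.9) overlapped such a peak of the control; 292 genes were then occupied against 1853, too few to compare gene lists. With lists of equal size the developmental list had 44 occupied genes, against 35 in the control and 39.1 in control-matched lists, and no longer stood apart from these (percentile 84.5), and with the 4000 strongest peaks of each list it had 4 against 4.

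In younger neurons, at DIV7, 33.2% of all protein-coding genes had a summit within 1 kb of a gene end, against 42.3% in the DIV14 control. The order turned in a 3 kb window (59.3% against 53.0%) and over all annotated genes (30.2% against 27.6%). Of the DIV7 summits 3.74% lay within 1 kb of a gene end, against 2.96% for shuffled peaks. As with TBC1D3, random placement gives most of this share, and a summit at a single gene is weak evidence. Within 1 kb the developmental list was occupied in 70 of 160 cases against 35, with Foxa2, Foxd4, Nkx2-6 and Hoxd1 among the 52 gained. Clustered protocadherin genes on chromosome 18 were occupied in 40 of 57 cases against 23, compared with 25 with TBC1D3 and 25 with MICAL1-M1. Both DIV7 differences lay at percentile 100 on length alone, and control-matched lists had 49.6 and 21.6 occupied genes (percentiles 99.98 and 100). Presynaptic release genes were occupied in 18 of 57 cases (31.6%, 19.9 to 45.2) against 40, a difference at percentile 0.15 of lists matched on length alone and 4.43 of control-matched lists. Postsynaptic glutamate genes were occupied in 32 of 60 cases against 44 (percentile 22.0 on length alone, 92.4 control-matched). Clustered histone genes were occupied in 18 of 67 cases against 45, ribosomal protein genes in 26 of 84 against 56, oxidative phosphorylation genes in 35 of 96 against 64 and Zfp genes in 143 of 394 against 229. On length alone these differences lay at percentiles 0, 0, 0 and 0.14, and among control-matched lists at percentiles 72.7, 17.0, 65.9 and 79.1. Axon guidance and immature neuron genes were occupied in 24 of 55 cases against 39 (percentile 4.43 on length alone, 52.7 control-matched), compared with 26 with TBC1D3 (8.73 and 69.7). The list of MICAL, RAB and actin regulators was occupied in 8 of 32 cases against 22 (percentile 0.185 on length alone, 6.69 control-matched), compared with 11 with TBC1D3 (2.24 and 34.4) and 19 with MICAL1-M1 (27.9 and 80.0). At equal list size 1 of its 32 genes was occupied at DIV7 (percentile 0 on length alone, 0.3 control-matched). With any base of a peak in the window 15 were occupied at DIV7 against 23 (percentile 11.9 on length alone). In a 3 kb window the numbers were 20 against 25 (percentile 3.55).

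Over the 21887 genes, 3430 were gained and 5411 lost at DIV7, and 3841 were occupied in both lists. A 3 kb window turned this order, with 5098 gained and 3727 lost. Lost synaptic genes included Ppfia2, an active zone scaffold gene (4.34-fold in the control), Snap25 and Bsn, the bassoon gene (3.51-fold each), and the adhesion gene Nlgn1 (3.29-fold). Syn1, the synapsin gene, was gained (2.19-fold in the DIV7 list). Syn1 lies on chromosome X, which held 0.418% of the control's peaks and 2.77% of the DIV7 peaks, so its gain goes with a difference over the whole chromosome. Immediate early genes were occupied in 20 of 37 cases against 29 (percentile 3.38 on length alone, 98.7 control-matched), with Jun, Klf4, Klf10 and Nr4a3 among the 14 lost. The highest control folds among lost genes were those of Triobp (5.92-fold), Ino80 (5.58-fold), Uap1 and Zfp869 (5.26-fold each) and Acvr1 (5.25-fold), then Ing1, Ints14, Jun and Zfp433 (5.04-fold each) and Zfand3 (4.96-fold). The highest DIV7 folds among gained genes were those of Arl13b, a ciliary GTPase gene, and Slc16a7, a monocarboxylate transporter gene (5.25-fold each), of Fgl2 and Thbd (4.82-fold each), and of Atpaf1, Casp6, Cdh22, Cep72, Runx1t1 and Slc35a3 (4.38-fold each). The 23 protocadherin genes occupied in the control rested on 3 peaks, because 1 peak can lie at the shared end of many protocadherin genes, and the 40 at DIV7 on 35 peaks. Microglia markers were occupied in 8 of 20 cases against 1 (percentile 99.9 on length alone, 85.9 control-matched), and fibroblast and endothelial markers in 10 of 20 against 6 (percentiles 98.7 and 94.4).

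Of the control's peaks, 12.1% (11.9 to 12.4) were overlapped by a peak of the DIV7 library, against 7.13% for shuffled peaks. At a q of at most 0.05 there were 415 DIV7 peaks on the assembled chromosomes, and 50 genes were occupied against 1853, too few to compare gene lists. With lists of equal size the developmental list had 37 occupied genes and the protocadherin list 24, against 35 and 23 in the control. Control-matched lists had 25.6 and 12.6 (percentiles 99.4 and 99.95). With the 4000 strongest peaks the developmental and protocadherin lists had 1 against 4 and 4 against 21. Over gene bodies the presynaptic list lay 5.26 percentage points above the control. The protocadherin rise was not particular to DIV7 under every setting. In a 3 kb window 53 of 57 were occupied at DIV7, 47 with TBC1D3 (percentile 100 on length alone) and 26 with MICAL1-M1, against 25 in the control. With any base of a peak in the window TBC1D3 had 31 against 24 (percentile 99.4), and DIV7 had 44.

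The synaptic and maturation genes fixed for naming behaved as follows across the 4 lists. Grin2a, Grin2b and Camk2a, genes of glutamate receptor subunits and of a calcium-dependent kinase, had a gene-end summit in every list. The peak at Grin2b reached a q of at most 0.05 in the control (3.72-fold) and in none of the other lists. Gria2 was occupied in the control and at DIV7. Tubb3, a neuronal tubulin gene, was occupied in the control and MICAL1-M1. Dlg4, which encodes the postsynaptic scaffold PSD-95, was occupied in MICAL1-M1 alone. Dcx, a gene of migrating neurons, was occupied in the control alone and Syn1 at DIV7 alone. Dcx and Syn1 lie on chromosome X. Its peak density was 0.0601 of the autosomes' density in the control, 0.262 with TBC1D3, 0.134 with MICAL1-M1 and 0.408 at DIV7. Absence of a summit at these genes therefore says little about them.

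In each of the 3 pairs, fewer genes were gained in common than a shared control gave in simulations without any effect. TBC1D3 and DIV7 gained 1149 genes in common, against 534 for independent lists and 1278 (1226 to 1365) in those simulations. TBC1D3 and MICAL1-M1 gained 1042 in common (395 for independent lists, 1382 simulated), and MICAL1-M1 and DIV7 gained 893 (398 and 1390). The pair of TBC1D3 and DIV7 lay closest to its simulated number. What made the observed numbers lower was not tested. At a q of at most 0.05, 114 of the 329 TBC1D3 peaks (34.7%, 29.5 to 40.1) overlapped such a peak of the DIV7 library and 20 (6.08%, 3.75 to 9.23) such a peak of the control. Without the 11 hotspot regions described with the closing observations, a step chosen after the data were seen, 87 of 299 TBC1D3 peaks (29.1%) overlapped a DIV7 peak. TBC1D3 and DIV7 also share a low background pileup (1.22 and 1.28) and short shortest peaks (227 and 230 bp). Of the 625 MICAL1-M1 peaks at this threshold, 29.1% overlapped a control peak, and those libraries share a higher depth. The overlap therefore cannot tell condition from depth or library preparation.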

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

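The q threshold of 0.05 behind these values, the 11 hotspot regions and both hotspot tests were chosen only after the result was seen. Outside the assembled chromosomes lie scaffolds and the mitochondrial genome, which the comparisons did not use. On scaffolds, peaks with a q of at most 0.05 were more frequent in the other libraries than in the control. The mitochondrial genome held 6 such peaks in the control, 0 with TBC1D3, 5 with MICAL1-M1 and 0 at DIV7. Unplaced or unlocalised scaffolds held 80 such peaks with TBC1D3, 19.6% of all (95% exact binomial interval 15.8 to 23.7), 25 with MICAL1-M1 (3.82%, 2.48 to 5.58) and 91 in mCherry at DIV7 (18.0%, 14.7 to 21.6), against 2 in the control (0.0494%).

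Hotspots were 11 regions of 57.0 kb in all, made by joining peaks with a -log10 q of at least 50 in any list that lay within 10 kb of each other, such as chromosome 9 from 3000011 to 3038303 and chromosome 2 from 98662240 to 98667441. By that definition they hold the strongest peaks of the lists they came from, so their share of these peaks is no finding. Their folds were read in the same lists that defined them, so the folds are no independent test either. Collapsed repeat copies, present alike in ChIP and input, would leave folds near 1, yet the median fold of the hotspot peaks, read within each list, was 6.34 (quartiles 4.27 to 6.63, n = 30) in the TBC1D3 list and 3.98 (3.49 to 4.22, n = 36) in the list of mCherry at DIV7, though 1.20 in the control's list and 1.78 in that of MICAL1-M1. Copy number alone stays open for the control and MICAL1-M1, and for TBC1D3 and DIV7 the folds argue against it only if input entered the caller's background, for which the labels are the sole source. ATRX binding at repeats, antibody yield and library preparation stay open for each list, and 1 library per group cannot separate them.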

How the results depend on the processing

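The q threshold of 0.05, the 4000 strongest peaks per list and random lists matched on control occupancy were chosen only after the result was seen; the other alternatives were fixed before. No paired analysis was possible because each group has 1 library, which also rules out leaving libraries out. Promoters by transcription start and matching on GC content were not run for lack of strand and sequence. Over all alternatives, 106 values of the main comparisons stayed within their counting interval or within 1.5 times the count, 105 moved beyond it and 6 changed direction or sign; among the other gene lists and percentiles 591 stayed, 169 moved and 11 changed sign. A sign against the control can follow the shift of all genes. Among lists matched on length, 14 of 69 list differences lay in the highest 2.5% and 12 in the lowest 2.5%. With matching on control occupancy as well, 4 and 0 of these stayed there. The 4 were developmental genes in the 3 comparisons and protocadherins at DIV7. The 3 comparisons share 1 control library, where the developmental list was low (21.9%, against 39.9% in random lists matched on length). Its 3 differences are therefore not independent. Within MICAL1-M1 its share lay at percentile 41.3 of lists matched on length. Merging peaks within 100 bp changed no value at all, so its 25 values among the 106 say nothing of stability, and adding all sequences moved none of the main values. Causes were not tested unless named. Values are given for TBC1D3, MICAL1-M1 and DIV7 in this order, and list differences are in percentage points against the control.

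At a q of at most 0.05 the peak number ratios to the control turned to 0.0814, 0.155 and 0.103, and 0.495%, 4.48% and 0.643% of the control's peaks were overlapped. Gene-end shares were 40.8% in the control and 9.42%, 41.6% and 11.1%. Gained genes numbered 23, 189 and 38, lost genes 1844, 1750 and 1841, and genes gained in common 3 for TBC1D3 with DIV7, 3 for TBC1D3 with MICAL1-M1 and 1 for MICAL1-M1 with DIV7, a pair order kept below. The presynaptic difference was -19.3 for MICAL1-M1 and -19.3 for DIV7, the developmental difference was -1.88, -1.88 and -2.50, and that of protocadherins at DIV7 -36.8. With 32, 292 and 50 occupied genes for 1853 in the control, a gene list loses nearly its whole control share, so these differences say nothing of the lists themselves.

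At a -log10 q of at least 5 the peak ratio of MICAL1-M1 turned to 0.440 and that of DIV7 was 1.41; 6.67%, 6.67% and 4% of control peaks were overlapped. Gene-end shares were 60% in the control and 4.44%, 9.09% and 1.89%. Gained genes numbered 7, 2 and 2, lost genes 49, 48 and 49, and common gains 2, 0 and 0. No presynaptic or postsynaptic gene was occupied in any library at this threshold, so the presynaptic difference was 0 for TBC1D3 and 0 for DIV7 and the postsynaptic one 0 for DIV7.

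With lists of equal size the peak ratios were 1, 1 and 1 by construction and 7.16%, 18.7% and 6.44% of control peaks were overlapped. Gene-end shares were 4.55%, 7.89% and 4.15%. Gained genes numbered 1862 for TBC1D3 and 1739 for DIV7, and common gains 361, 497 and 379. The postsynaptic difference was -31.7 for TBC1D3 and -45.0 for DIV7, and the presynaptic one -49.1 for DIV7. The developmental difference shrank to 6.88, 5.63 and 1.25, at percentiles 99.8, 84.5 and 99.4 with matching on control occupancy. That of fibroblast and endothelial markers with TBC1D3 was -15 (percentile 30.9). With the 4000 strongest peaks 3.28%, 16.5% and 2.53% of control peaks were overlapped, and gene-end shares were 40.9% in the control and 10.2%, 29.4% and 6.45%. Gained genes numbered 347, 939 and 223, lost genes 1750, 1482 and 1783, and common gains 11, 54 and 34. At DIV7 the presynaptic difference was -19.3, and those of protocadherins and of the developmental list were -29.8 and -1.88. The developmental difference was 0 with TBC1D3 and 0 with MICAL1-M1, with 4 of 160 genes occupied in each as in the control.

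With an overlap of 50% of both peaks 3.63%, 8.14% and 3.63% of control peaks were shared, and with summits within 100 bp 2.99%, 4.88% and 2.92%. In a 3 kb window gene-end shares were 16.1% in the control and 9.04%, 11.8% and 8.60%. Gained genes numbered 4774, 2710 and 5098, lost genes 3760, 2671 and 3727, and common gains 2763, 1666 and 1618. Over all annotated genes, a larger set by construction, 8913, 5591 and 9460 were gained, 8116, 5497 and 8188 lost, and 2917, 2104 and 1880 gained in common. Where the other library had no summit within 5 kb, 2196, 1360 and 2254 were gained, 1983, 1530 and 1942 lost, and 665, 515 and 416 gained in common.

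Over gene bodies the postsynaptic difference was 5 for TBC1D3 and 0 for DIV7. The presynaptic difference was 7.02 for TBC1D3 and 5.26 for DIV7, against 8.12 and 8.99 in random lists. Chromatin genes had 3.13 and 10.9 (10.4 and 11.8 in random lists), and channels at DIV7 2.17 (7.18). Zfp genes had 4.31 and 4.82 (10.9 and 12.4). These sign changes come with a rise over all genes, from 57.2% occupied in the control to 66.6% with TBC1D3 and 67.7% at DIV7. With a background pileup of 1.22 in TBC1D3 and 1.28 at DIV7, a call could rest on 3 fragments. The presence of a gene in those lists, and so its gain, is therefore weak evidence. Its absence is weak evidence too, since the depth was low. At a q of at most 0.05 the developmental list gained 0, 0 and 0 genes and lost 3, 3 and 4.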

Other observations

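Of the tests in this part, those of library preparation, of the X range against the ranges of autosomes, of gene lists matched on control occupancy and of the depth prediction from each site's own background were chosen only after the result was seen. Olfactory receptor genes were occupied at gene ends in 10 of 1106 cases in the control, 131 with TBC1D3, 23 with MICAL1-M1 and 181 at DIV7, and vomeronasal receptor genes in 4, 24, 5 and 58 of 353. Every one of these shares lay at or near percentile 0 of the length-matched random lists, so the receptor genes were sparsely occupied in all 4 libraries. Olfactory genes lay further above the control with TBC1D3 and at DIV7 than any list matched on length (percentile 100 in both), and vomeronasal genes further than nearly all such lists. Random lists as rarely occupied in the control had more occupied genes, however, 178 and 206 for the 131 and 181 olfactory genes (percentiles 0 and 0.665), and vomeronasal genes lay at percentiles 0 and 0.51. Imprinted genes were occupied in 13 of 41 cases in the control, 18 with TBC1D3, 18 with MICAL1-M1 and 17 at DIV7, at percentiles 98.6, 97.1 and 97.6 of lists matched on length and 91.0, 85.7 and 84.9 of lists matched on control occupancy too, and in 13, 14 and 10 cases against 13 with lists of equal size. Dlk1 and Dio3, neighbours in an imprinted domain, were gained with TBC1D3 and at DIV7.

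Voltage-gated channel genes were occupied in 34 of 46 cases in the control, 31 with TBC1D3, 28 with MICAL1-M1 and 23 at DIV7, and genes of inhibitory synapses and interneurons in 22, 18, 24 and 16 of 38. Neuronal adhesion genes were occupied in 36, 27, 34 and 26 of 48 cases, and genes of chromatin and ATRX partners in 38, 25, 39 and 23 of 64, with Trim28 lost in MICAL1-M1 and at DIV7. None of the differences of these 4 lists lay below percentile 10.4 or above 83.5 of lists matched on length; with matching on control occupancy the percentiles ran from 32.1 to 99.9, the highest for channel genes with TBC1D3 (96.9 with lists of equal size). Markers of astrocytes were occupied in 11, 8, 9 and 11 of 20 cases, those of oligodendrocytes in 10, 8, 11 and 7 of 20, and those of progenitors in 14, 14, 15 and 15 of 32. At a q of at most 0.05, TBC1D3 and DIV7 had 3 gained genes in common (Gm36327, Lars2 and Asmt), TBC1D3 and MICAL1-M1 had 3 (Dner, Slc30a4 and Psip1), and MICAL1-M1 and DIV7 had 1 (Slc16a7). These genes were named after their values were seen.

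Fewer of the control's 4041 peaks with a q of at most 0.05 had a peak in the full TBC1D3 list (32.1%, 30.7 to 33.6) and DIV7 list (30.2%, 28.8 to 31.7) than in the MICAL1-M1 list (63.6%, 62.1 to 65.1). Thinning the MICAL1-M1 pileup at these sites to the lower depth predicted 50.1% for TBC1D3 and 51.4% for DIV7 with each site's own background, and 55.1% and 56.8% with the genome background, which argues against lower depth alone. TBC1D3 and DIV7 also had the shortest peaks and the lowest gene-end shares, with a gap of 2.42 percentage points between MICAL1-M1 (6.49%) and TBC1D3 (4.07%). Library preparation and condition cannot be told apart here, because each condition has 1 library. A resemblance between TBC1D3 neurons and younger neurons in ATRX occupancy is a hypothesis that these lists leave open, as is a lower ChIP yield in both.

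Chromosome X held few peaks, 0.418% of those of the control, 1.79% with TBC1D3, 0.924% with MICAL1-M1 and 2.77% at DIV7, for 6.30% of the searched length. Near the noise level a lower X dosage may remove most calls, and the dosage implied by the peak density was 0.554, 0.564, 0.558 and 0.672 in that order. Its range of 0.118 exceeded the bound of 0.1 set for a common dosage, and the ranges of the 19 autosomes ran from 0.00255 to 0.0596. This argues against one dosage in all 4 libraries, and the value of DIV7 alone makes the range. Chromosome Y held 0.0135%, 0.0543%, 0.0134% and 0.109% of peaks in the same order, also highest at DIV7. A different share of male and female embryos between cultures was not tested.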
